A study of Macaca mulatta with 13 samples.

How the data were processed

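Gene expression was measured in peripheral blood mononuclear cells, the lymphocytes, monocytes and other single-nucleus cells of the blood, from 13 rhesus macaques at 4 months of age. Total RNA of each animal was labelled with biotin and hybridised to 1 Affymetrix rhesus genome array, per the labels. The labels give 5 animals as maternally reared, 4 as peer reared and 4 as surrogate-peer reared. Sex, collection batch and scan batch were not used here because the labels do not name them. Each sample title ends in a number whose meaning the labels do not state; it was used only as a covariate in an alternative.

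The values are log2 expression values per probe set, made by the authors with robust multi-array average (RMA), per the submitters' processing notes; the RMA version, its settings and the array annotation are not given in the sources used here. Whether the 13 arrays were normalized together is not given either, and the spread of values of the maternal arrays differs from that of the others, so a difference left by normalization would be part of every fold change against the maternal animals. The scale was taken as log2 from the deposited values themselves. The median of an array lay between 6.00 and 6.06. An array has no read depth, so the number of arrays limits the precision. The table held 52865 probe sets, of which 158 control probe sets were left out of all tests, leaving 52707. A probe set was tested when its mean over the 13 arrays was above the median of those means, 6.04 on the log2 scale, which left 26352. Of the 52707 probe sets, 24956 were paired with 1 gene symbol by the platform annotation, 361 with several and 27390 with none; a gene was named only from a probe set with 1 symbol. Among tested probe sets 15332, or 58.2%, carried 1 symbol, for 9657 genes.

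Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 13 arrays in 1 fit, so that the groups shared an estimate of the spread. Where maternal values vary more than the others, a shared estimate makes the errors and p-values against maternal animals too small. Adjusted p-values are two-sided, by Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05. Contrasts were the mean of the peer and surrogate-peer groups minus the maternal group, each of these groups minus the maternal group, and surrogate-peer minus peer; a moderated F test asked whether any group differed. Errors of log2 fold changes are standard errors of the fit.

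For each comparison the named genes were the up to 10 highest and up to 10 lowest log2 fold changes past the threshold, with 1 probe set per gene, the one with the smallest p, and symbols starting with LOC left out. Where fewer than 5 passed in a direction, the 5 with the smallest p were named. Another 25 lists of genes, 9 of cell type markers and 16 of processes, held 631 genes, of which 371 were measured; each member was represented by the probe set with the highest mean. From each list, up to 8 members past the threshold over the list alone were eligible to be named, and otherwise the 3 with the smallest p. A list score is the mean over the members of the log2 value minus the member's mean over the 13 arrays. Scores were compared between groups with an exact two-sided permutation test, adjusted over the 25 lists. The smallest p this test can give is 7.77e-04 for the 8 non-maternal against the 5 maternal animals, 0.00794 for 4 against 5 and 0.0286 for 4 against 4. With 4 against 5 a single list at that smallest p has an adjusted p of 0.198 over the 25 lists. A list that differs alone can therefore not pass there, and a count of 0 lists says little. The limma functions camera, with a preset correlation of 0.01 and with an estimated one, and fry were alternatives. The PValue of fry asks whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. The groups, tests, lists and rule for named genes were fixed before the data were examined. A list of sex-linked genes had 0 members among probe sets with 1 symbol in the annotation used and gave no result.

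The ratio of 3' to 5' signal was the mean over the actin and GAPDH control probe sets of the log2 value at the 3' end minus that at the 5' end. Control signals, the spread and median of array values and the title number made a family of 28 exact permutation tests.

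Tests were checked on simulated data with 26352 probe sets, drawn from the real means and residual SDs with 200 changed probe sets per comparison. For the non-maternal against the maternal groups limma called 67.2% of the probe sets changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 3-fold, and 9 unchanged ones; the 3 other comparisons below had 16, 9 and 13 unchanged calls. For peer against maternal it called 52.2%, 80.6% and 93.9%, for surrogate-peer against maternal 49.3%, 80.6% and 95.5%, and for surrogate-peer against peer 38.8%, 71.6% and 93.9%, at the same folds. The list test called 13, 11, 12 and 0 of 13 shifted lists in the 4 comparisons, taken in that order, for a shift of 0.5 on the log2 scale; the last cannot pass the adjustment because 4 animals were set against 4. Simulated probe sets were independent, which real ones are not.

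Alternatives covered the filter, array centring, quantile normalization, moderation of the variance, array weights, the unit tested, the threshold, covariates, the arrays in the fit and leaving out each array in turn. Figures were drawn with matplotlib.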

Results

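Gene expression in blood mononuclear cells of 4-month-old rhesus macaques was compared between animals reared by their mothers (n = 5), with peers (n = 4) or under surrogate-peer rearing (n = 4). The series asks whether expression differs by early rearing condition. Each animal contributed 1 array, and correlations of an array with the other 12 averaged between 0.934 for maternal array 5 and 0.971 for surrogate-peer array 4. The 3' to 5' log2 ratio was 1.85 ± 0.28 (SD, n = 5) in maternal animals and 1.45 ± 0.14 (SD, n = 8) in the others (exact permutation p = 0.00466, adjusted p = 0.0278). The SD of all log2 values of an array ran from 2.10 to 2.12 in maternal and from 2.13 to 2.16 in non-maternal arrays, without overlap (exact permutation p = 7.77e-04, the smallest this test can give). Array medians did not overlap either, 6.048 to 6.06 in maternal and 5.995 to 6.043 in other arrays (exact permutation, adjusted p = 0.0278). Title numbers were 9 to 32 in surrogate-peer, 35 to 47 in peer and 31 to 55 in maternal animals. The BioB hybridisation control was 9.30 to 9.39 in surrogate-peer and 8.86 to 9.28 in peer arrays. For both measures surrogate-peer against peer gave an exact permutation p = 0.0286 (adjusted p = 0.0571).

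**Figure D1:**
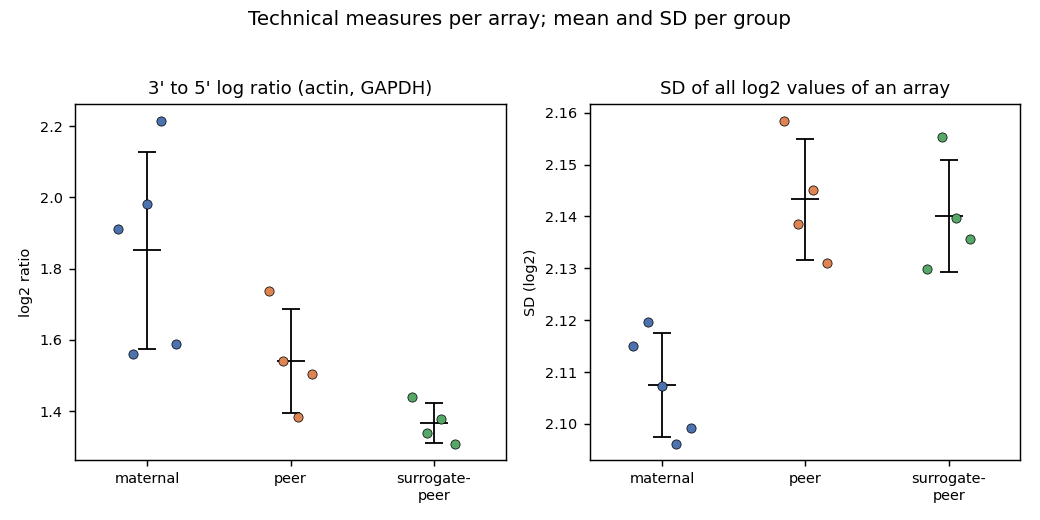
Each point is 1 array, grouped by rearing; the left panel shows the 3' to 5' log2 ratio of the actin and GAPDH control probe sets and the right panel the SD of all log2 values of the array, with bars for the group mean and SD. The right panel shows no overlap between the maternal arrays and the 8 others, while the left panel overlaps.

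The first comparison set the peer and surrogate-peer animals together against the maternal animals. GZMH (log2 fold change -1.61 ± 0.35, SE) and GZMB (-1.37 ± 0.24), granzyme genes of cytotoxic lymphocytes, fell, and so did KLRC1, which encodes the inhibitory NK receptor NKG2A (-1.38 ± 0.32), and FCGR3, the low-affinity IgG receptor CD16 (-1.20 ± 0.29). Rising genes included EGR2, a transcription factor induced by T cell receptor signalling (2.59 ± 0.53), FCER1A, the alpha chain of the IgE receptor of basophils and dendritic cells (1.91 ± 0.45), and CPA3, a protease of mast cells and basophils (1.34 ± 0.36). GZMB averaged 12.62 ± 0.32 (SD, n = 5) on the log2 scale in maternal, 11.31 ± 0.41 (SD, n = 4) in peer and 11.19 ± 0.65 (SD, n = 4) in surrogate-peer animals. EGR2 averaged 5.60 ± 0.31, 8.24 ± 1.04 and 8.14 ± 1.57 in the same groups.

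In all, 2107 of 26352 probe sets passed the threshold of limma, 1751 higher and 356 lower in the non-maternal animals, covering 1118 named genes. The other rising genes with the largest changes were CLSPN, a replication checkpoint adaptor (2.62 ± 0.66), CDK2AP1 (1.21 ± 0.29), GPRASP1 (1.20 ± 0.27), SLC35G1 (1.20 ± 0.21), IL6ST, the shared receptor subunit of the interleukin-6 family (1.12 ± 0.25), CA6 (1.06 ± 0.24) and GASK1B (1.05 ± 0.28). Among falling genes were MS4A7, a membrane protein of monocytes (-1.48 ± 0.35), CCRL2, an atypical chemokine receptor (-1.43 ± 0.40), SLC25A37, a mitochondrial iron importer (-1.37 ± 0.32), the collagen gene COL11A1 (-1.35 ± 0.19), and GBP1, an interferon-induced GTPase (-1.29 ± 0.36). The regulator of interferon genes IRF7 fell at 1 probe set (-1.21 ± 0.32), while its brighter probe set gave 0.04. All 8 non-maternal values of GZMH, GZMB, COL11A1, FCER1A and SLC35G1 lay beyond every maternal value, and adjusted p for these 20 genes ran from 0.0150 for COL11A1 to 0.0490 for GBP1. Over all 26352 tested probe sets, called or not, 755 (2.87%) had the 8 arrays wholly on 1 side of the 5 maternal arrays, where chance gives 0.155%; probe sets are not independent of each other.

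Leaving out single arrays changed this count by more than 1.5 times in each of 13 cases: 4823 without maternal array 1, 1218, 1198, 30 and 60 without maternal arrays 2 to 5, 309, 715, 985 and 886 without peer arrays 1 to 4, and 1376, 1322, 474 and 1221 without surrogate-peer arrays 1 to 4. The share of higher calls was 83.1% as deposited, 56.7% after centring each array on the median of its tested probe sets (1094 higher, 834 lower) and 66.2% after a further quantile normalization (883 higher, 450 lower). The spread was not equal between groups. Array weights of limma, lower for more variable arrays, were 0.42 to 0.88 for maternal and 0.56 to 2.65 for other arrays. With them 1598 probe sets passed. IL6ST had an SD of 0.68 in maternal, 0.08 in peer and 0.37 in surrogate-peer animals, while for GZMB the maternal SD was the smallest. For genes like IL6ST the shared estimate understates the maternal spread.

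**Figure D2:**
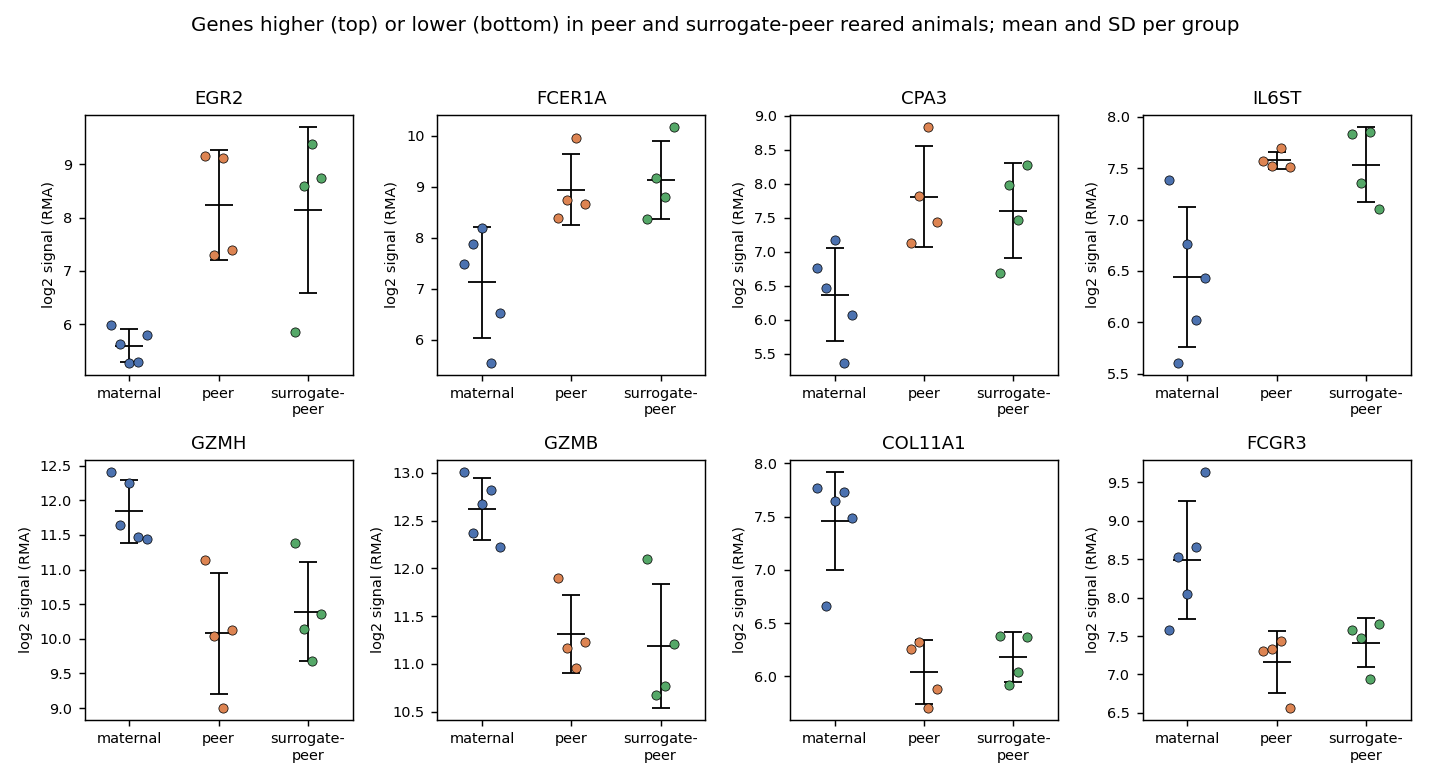
Each point is the log2 signal of 1 array for 8 named genes, grouped by rearing, with bars for the group mean and SD. The upper genes lie higher and the lower genes lower in the peer and surrogate-peer groups; the 8 non-maternal values of GZMB, GZMH and COL11A1 lie below every maternal value, and EGR2 has 1 surrogate-peer value within the maternal range.

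For scale, 2107 of all 26352 tested probe sets passed, and 7647 had an unadjusted limma p under 0.05, where chance gives 1318. A few members passing, above all adjusted over a list alone, are therefore not by themselves particular to that list. This holds for the list counts here and in the later comparisons with maternal animals. Among 17 measured markers of NK and cytotoxic cells, 5 fell and 1 rose over all genes tested, and 7 fell and 1 rose when adjusted over the list alone. Those that fell over all genes were GZMB, GZMH, FCGR3, CST7, a cystatin of cytotoxic granules (-0.92), and NKG7 (-1.01). NCAM1, the adhesion molecule CD56, rose (0.48), while its other probe sets gave 0.02 to 0.41 and did not pass. TBX21, the transcription factor T-bet (-0.63), and KLRF1 (-0.81) passed over the list alone. The list score differed by -0.59 (exact permutation p = 0.0256, adjusted p = 0.136).

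T cell markers had positive fold changes in 13 of 14 measured members, with 1 rising over all genes and 5 adjusted over the list alone, at the brightest probe set of each gene. BCL11B, a transcription factor of T cell identity, rose (0.70). CD8B (0.75) and TCF7 (0.63) passed over the list alone; so did CD8A (0.64) and TRAT1 (0.71), each of which rose over all genes at another probe set (0.89 and 0.83). The score was higher by 0.37 (exact permutation p = 0.0117, adjusted p = 0.136). It was lowest on maternal arrays 2 and 5 (-0.54 and -0.53), where the monocyte marker score was highest, and without these arrays, an alternative added after seeing the data, the difference was 0.17. In the T cell activation list, EGR2 and LAT, an adaptor of the T cell receptor (0.50), rose, 2 of 18 members by both adjustments, and the score difference was 0.29 (exact permutation p = 0.0155, adjusted p = 0.136), or 0.14 without the same arrays. A large part of the 0.29, a mean over 18 members, came from EGR2 (2.59). The other probe sets of LAT gave 0.25 and 0.28 and did not pass. CCR7 (0.73), a homing receptor of naive T cells, passed over its list alone, with CCR3 (0.98), while CX3CR1 (-0.30) and SELPLG (-0.69) fell; the chemokine receptor and homing list thus had 0 up and 2 down of 11 over all genes, and 2 up and 2 down adjusted over the list alone.

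Of 26 interferon type I response genes, 24 had negative fold changes, and 1, ISG20 (-0.39), fell by both adjustments. IFIT1 (-2.11) and ISG15 (-1.16), antiviral effectors with larger changes, had adjusted p of 0.0602 and 0.0687 and did not pass. The score difference was -0.63 ± 0.38 (SE, exact permutation p = 0.0637, adjusted p = 0.196). The 5 maternal scores were spread widely: 1.27 and 1.30 on arrays 2 and 5, against -0.37, -0.26 and 7.37e-04 on arrays 1, 3 and 4. The monocyte marker score was 0.79 on both arrays 2 and 5 as well. In the list of interferon gamma response and class I presentation, 14 of 15 members were negative, and GBP1, TAP2, a peptide transporter subunit (-0.52), and TAPBP (-0.28) fell by both adjustments; its score difference was -0.32 (exact permutation p = 0.0311, adjusted p = 0.136). Leaving out maternal array 2 or 5 alone brought the type I difference to -0.41 or -0.40. Without both, the type I difference was -0.03 and the interferon gamma difference -0.16, while that of NK and cytotoxic markers was -0.83. In that setting 37 probe sets passed in the whole comparison, 28 of them among the 2107. All 2102 of the 2107 that were still tested had the same sign, which the shared arrays make likely.

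Transcription factors of the NF-kB and AP-1 families counted 3 down of 13 over all genes and 5 down adjusted over the list alone. NFKBIE (-0.31), an inhibitor of NF-kB, ATF3 (-0.40) and BCL3 (-0.74) fell, and JUND (-0.42) and FOSL2 (-0.96) passed over the list alone. The list score gave -0.14 (exact permutation p = 0.176, adjusted p = 0.314), or -0.09 without maternal array 5. Glucocorticoid receptor targets had 2 down of 15 over all genes, TSC22D3, the leucine zipper protein GILZ (-0.61), and TXNIP (-0.50). Adjusted over the list alone, 5 were down, with PER1 (-0.30), CEBPB (-0.75) and ZBTB16 (-0.71), and 1 was up, THBD (0.40; another of its 3 probe sets gave -0.50); the score difference was -0.24 (exact permutation p = 0.0707, adjusted p = 0.196). Of 12 immediate early and heat shock genes, EGR2 rose and ATF3 and IER5 (-0.61) fell, by both adjustments, and the score difference was 0.23 (exact permutation p = 0.152). Nearly all of this mean over 12 members came from EGR2 (2.59).

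Adrenergic and cyclic AMP signalling counted 2 up of 17 over all genes, the phosphodiesterase gene PDE7A (0.69) and ATF1 (0.37). Adjusted over the list alone, PRKACB (0.58), CREB1 (0.34) and PDE3B (0.33) were up as well and PDE4A (-0.31) was down. For ATF1, 1 of 5 probe sets had the opposite sign (-0.08). The mean change of this list was 0.08 and its median -0.06. The mean was 0.04 without maternal array 2 and 0.004 without maternal arrays 2 and 5. Cytokines and their receptors had 2 up of 26 over all genes, IL6ST and IL23A (0.48), and 3 up and 3 down adjusted over the list alone: TGFBR2 (0.36, and 0.49 at another probe set, which passed over all genes) was up, and CSF3R (-0.99), TNFRSF1B (-0.67) and IL1RAP (-0.62) were down. Ribosomal protein genes had 2 up of 25 by both adjustments, RPL32 (0.47) and RPL15 (0.24), with a score difference of 0.09 (exact permutation p = 0.0241, adjusted p = 0.136), which was 0.05 without maternal array 5 and 0.03 without arrays 2 and 5.

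B cell markers had 1 of 12 down over all genes, FCRLA (-0.92), and 5 adjusted over the list alone, and MS4A1, the antigen CD20 (-0.70), fell over all genes at another probe set (-1.07). The B cell score differed by -0.11 in peer animals (exact permutation p = 0.675, with 4 of 12 members positive) and by -0.88 in surrogate-peer animals. Without maternal array 2 the peer difference was 0.04 and the surrogate-peer difference -0.72. Plasma cell markers had 1 of 11 down, PRDM1 (-0.73), and 2 adjusted over the list alone.

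These counts take the brightest probe set of each member, and for 12 genes of the lists another probe set passed where that one did not. Besides CD8A, TRAT1, TGFBR2, MS4A1, KLRC1 and IRF7, they were TNFAIP3, an inhibitor of NF-kB signalling (0.15, against 0.60 and 0.66), the T cell activation genes CD40LG (0.48, against 0.63) and IL2RG (0.06, against 0.39), the glucocorticoid receptor gene NR3C1 (-0.01, against 0.37), UQCRC1 of the respiratory chain (-0.03, against 0.50) and GNLY (-0.87, against -0.42). All were chosen by this difference after their values were seen.

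The exact test called 0 of 25 lists, with 6 at an unadjusted p under 0.05. Camera with the preset correlation called 10 of 25 lists, fry called 0, and 15 passed by the mixed test of fry. With an estimated correlation camera called 0 lists, with an adjusted p = 0.608 with an estimated correlation for each of the groups above except immediate early and heat shock (0.945) and adrenergic signalling (0.987). Without peer array 4 the exact test called 1 list, the plasma cell markers (adjusted p = 0.0316).

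**Figure D3:**
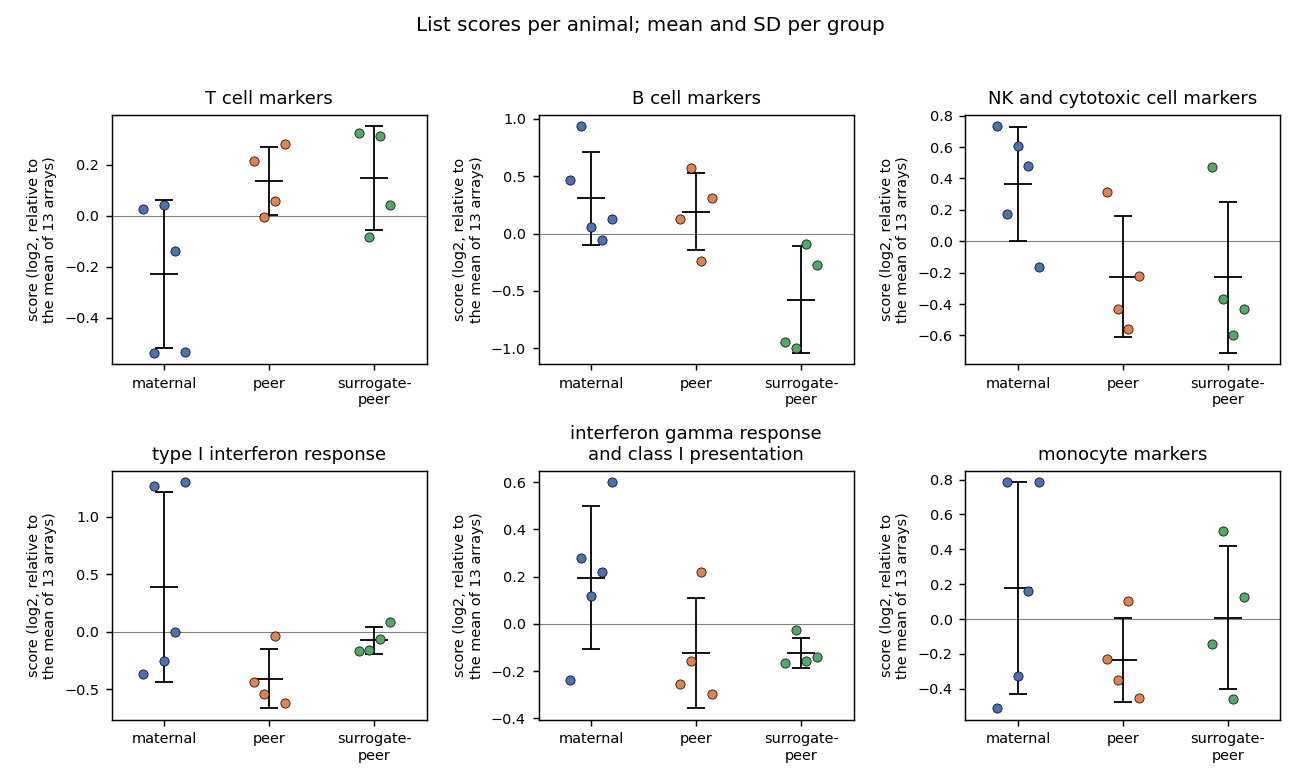
Each point is the score of 1 animal for 6 of the lists, on the log2 scale relative to the mean of the 13 arrays, with bars for the group mean and SD. Maternal arrays 2 and 5 have the highest type I interferon and monocyte scores, and surrogate-peer arrays 1 and 2 the lowest B cell scores (-0.95 and -0.996).

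Peer rearing was then compared with maternal rearing. Among the genes with the largest changes POLR1C, a subunit of RNA polymerases I and III (1.09 ± 0.15), PRMT6, an arginine methyltransferase (0.88 ± 0.15), RBM48 (0.87 ± 0.16), TNPO1, a nuclear import receptor (0.85 ± 0.15; its other probe sets gave 0.66 and -0.06), and AHCTF1, a nuclear pore assembly factor (0.90 ± 0.15; its other probe sets gave 0.28 and 0.00), rose. SLC35G1 (1.28 ± 0.24), ZNF397 (0.93 ± 0.17; other probe set 0.06), ABTB3 (0.89 ± 0.14; other probe set 0.43), RAB11FIP2 (0.86 ± 0.16) and VMA21 (0.85 ± 0.15) also rose. COL11A1 (-1.42 ± 0.22), CST7 (-1.14 ± 0.22), the corepressor gene TLE3 (-0.62 ± 0.11; its 3 other probe sets ran from -0.33 to -0.14) and the transcriptional regulator HES6 (-0.51 ± 0.09) fell. GNLY, encoding the cytolytic protein granulysin, did not pass (-0.49 ± 0.09, adjusted p = 0.0501). These named genes, apart from GNLY, had adjusted p of 0.0343 for POLR1C and 0.0486 for the rest.

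In this contrast 93 probe sets passed, 82 higher and 11 lower, for 44 named genes, and all 93 were also called in the first comparison, which contains the same peer and maternal arrays. Of the 26352 tested probe sets, 6571 had an unadjusted limma p under 0.05. Among NK and cytotoxic markers 1 of 17, CST7, fell over all genes, and 8 were down and 1 up adjusted over the list alone; GZMB gave -1.31 and GZMH -1.76. The type I interferon list had 0 over all genes and 4 down adjusted over the list alone, IFIT1 (-2.96), ISG15 (-1.38), IFI27 (-1.16) and ISG20 (-0.37). Its score difference was -0.80, or -0.20 without maternal arrays 2 and 5. T cell markers had 0 over all genes and 4 up adjusted over the list alone, among them CD8B (0.86) and CD8A (0.68). The exact test called 0 of 25 lists, with 0 at an unadjusted p under 0.05; camera with the preset correlation called 8, and camera with an estimated correlation and fry called 0. The count of probe sets fell to 0 with only the 9 arrays compared, and leaving out single arrays gave 3484, 6, 0, 0 and 4 for maternal arrays 1 to 5, 1, 1, 0 and 0 for peer arrays 1 to 4, and 0, 6, 17 and 5 for surrogate-peer arrays 1 to 4.

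Surrogate-peer rearing was compared with maternal rearing in the same way. B cell markers stood lowest here: all 12 measured members had negative fold changes, and 9 were down adjusted over the list alone, with 0 over all genes. They included FCRLA (-1.17), the B cell receptor chains CD79B (-1.25) and CD79A (-0.54), the adaptor BLNK (-1.24), CD22 (-1.23), MS4A1 (-1.19), the transcription factor EBF1 (-1.21) and the kinase BLK (-0.59). The score was lower by -0.88 ± 0.29 (SE, exact permutation p = 0.00794, the smallest possible, adjusted p = 0.198). The 4 surrogate-peer scores were -0.95, -0.996, -0.09 and -0.27, and the maternal scores ran from -0.05 to 0.94.

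No probe set passed limma's threshold: the count was 0, with 5345 at an unadjusted p under 0.05, where chance gives 1318, and a smallest adjusted p of 0.0520. The genes with the smallest p were ABHD10 (0.49 ± 0.07), XRCC6, the Ku70 subunit of DNA end joining (0.71 ± 0.11), AVL9 (0.69 ± 0.11), NAP1L4 (0.62 ± 0.10) and TDP2 (0.48 ± 0.08) with positive values, and TLE3 (-0.84 ± 0.11), HES6 (-0.58 ± 0.09), the DNA polymerase delta gene POLD1 (-0.99 ± 0.17), ERGIC1 (-0.68 ± 0.12) and TXNL4B (-0.62 ± 0.11) with negative values. For XRCC6, AVL9 and NAP1L4, 1 probe set each had the opposite sign. NK and cytotoxic markers had 5 of 17 down adjusted over the list alone and 0 over all genes, with GZMB at -1.43. MHC class II genes had 2 of 8 down adjusted over the list alone, MAMU-DQB1 (-2.05) and IFI30 (-0.69), and 0 over all genes. Plasma cell markers had 2 of 11 down over the list alone and 0 over all genes, MZB1 (-0.96) and PRDM1 (-0.81), with a score difference of -0.25 (exact permutation p = 0.0238, adjusted p = 0.298). Of 9 dendritic cell markers FCER1A (2.01) was up and CD1C (-0.78) and CD83 (-0.61) were down over the list alone, with 0 over all genes.

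The exact test called 0 of 25 lists, with 2 at an unadjusted p under 0.05; camera with the preset correlation called 8, among them the B cell list, whose adjusted p = 0.613 with an estimated correlation. Without maternal array 1 the count of probe sets rose from 0 to 2095, without maternal array 2 to 1 and without peer array 2 to 2, and with the monocyte score as a covariate to 534.

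Surrogate-peer and peer animals were compared directly. B cell markers had negative fold changes in all 12 members, 10 of them past the threshold adjusted over the list alone and 0 over all genes, and the score differed by -0.77 ± 0.29 (SE, exact permutation p = 0.0571, adjusted p = 0.714). The surrogate-peer and peer arrays also did not overlap in title number or in the BioB control. Rearing cannot be told apart here from what those measures reflect. Limma called 0 probe sets, with 483 at an unadjusted p under 0.05, where chance gives 1318. The genes with the smallest p were GIPC2 (1.19), SERPINB2 (1.22), CD81 (0.27), TSPAN32 (0.61) and CLN3 (0.22), higher with surrogate-peer rearing, and POLR1C (-0.76), KLHL24 (-0.81), XKRX (-1.25), RALGPS2 (-0.78) and HS3ST1 (-0.69), lower; none passed, with an adjusted p of 0.99994. For KLHL24, 1 of 3 probe sets had the opposite sign. The exact test called 0 of 25 lists, with 0 at an unadjusted p under 0.05, while camera with the preset correlation called 5, and camera with an estimated correlation and fry called 0.

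Across the 3 groups, the moderated F test called 23 probe sets for 10 named genes, and all 23 were also called for the non-maternal against the maternal animals. Without maternal array 1 the F test called 2318, without maternal array 2, maternal array 5 or peer array 2 it called 1, and without any other array 0. The fold changes of peer and of surrogate-peer against maternal animals correlated across tested probe sets with r = 0.850 and a covariance of 0.0795; probe sets are not independent replicates. Unchanged groups sharing the 5 maternal arrays gave r = 0.443 and a covariance of 0.0186 in simulations, a difference in covariance of 0.0609. The simulated probe sets were independent and had the same spread on every array, while the maternal arrays had array weights of only 0.42 to 0.88. The simulated covariance may thus be too low, and the difference cannot be read as an effect beyond the shared arrays. With the maternal arrays split into sets of 2 and 3, the 20 splits gave r between 0.106 and 0.71, with a median of 0.559.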

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

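In groups of 4 or 5 animals, a value was singled out when its gap to the nearest other value was large relative to the range of the group (Dixon's test). Of 243 groups tested over 81 scores, control measures and named genes, 15 met this, where chance gives about 12.15. Surrogate-peer array 1 had an NF-kB and AP-1 score of -0.30, against -0.01 on the 3 other arrays of its group. Maternal array 5 had an oxidative phosphorylation score of -0.41, with the other maternal arrays between -0.09 and 0.03. Peer array 1 had a red cell marker score of 0.75, with the others between -0.29 and -0.20. The BioB hybridisation control was 9.39 on surrogate-peer array 2, against 9.30 to 9.31 on the others.

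Among named genes, COL11A1 was 6.66 on maternal array 2, where the other maternal arrays lay between 7.49 and 7.77. FCGR3 was 6.57 on peer array 4, POLR1C 7.95, TXNL4B 8.20 and CLN3 8.32 on the same array. On peer array 3, POLD1 was 7.96 and XKRX 7.83. GIPC2 was 6.80 on peer array 2, and TSPAN32 was 7.50 on maternal array 5. AVL9 was 6.01 on maternal array 1 and 6.13 on surrogate-peer array 4.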

How the results depend on the processing

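The added alternatives, the 3' to 5' ratio as a covariate and maternal arrays 2 and 5 left out together, were chosen after seeing the data. The Y-linked covariate was not run, because the annotation used gives no sex-linked gene on the list as the symbol of a probe set. No paired analysis was possible because the labels give no number shared between animals of different groups. The cause of the changes below was not tested unless the setting itself tests fewer probe sets or arrays.

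The 2107 probe sets called for the non-maternal against the maternal animals were 1333 after quantile normalization, 828 with 1 probe set per gene, 4650 at an adjusted p under 0.10 and 37 without maternal arrays 2 and 5; leaving out 1 array gave 30 to 4823. Every one of the 2107 that was tested kept its sign in each setting that refitted the probe sets. The settings share most or all arrays with the fit that chose these probe sets, so kept signs were likely and are weak support. With the 3' to 5' covariate 1566 were called, 665 of the 2107 among them, and the fold changes were a median 1.10 times those without it.

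The 23 probe sets of the F test were 15 with no filter, 4 with array weights, 1014 at an adjusted p under 0.10, 108 and 749 with the monocyte and title number covariates, 1 without maternal arrays 2 and 5, and 0 with the 75th percentile filter, array centring, quantile normalization, 1 probe set per gene or the 3' to 5' covariate (leave-one-out 0 to 2318). The 93 for peer against maternal were 50 with no filter, 1 with the 75th percentile filter, 5 centred, 6 quantile normalized, 59 with trend and robust moderation, 1543 with array weights, 0 with 1 probe set per gene, 2499 at 0.10, 1820 by a 1.5-fold difference with no p, 11, 1819 and 1445 with the monocyte, title number and 3' to 5' covariates, 0 with only the arrays compared and 3 without maternal arrays 2 and 5 (leave-one-out 0 to 3484). The 0 for surrogate-peer against maternal were 1 with no filter, 33 centred, 25 quantile normalized, 620 at 0.10, 1433 by fold, 534, 7 and 4 with the same 3 covariates and 1 without maternal arrays 2 and 5 (leave-one-out 0 to 2095). Surrogate-peer against peer stayed at 0 except for 331 by fold (leave-one-out 0 to 0).

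Camera with the preset correlation called 10, 8, 8 and 5 lists in the 4 comparisons, where the exact test called 0, as did camera with an estimated correlation in all 4. Fry with the title number called 5 for the non-maternal animals, with the monocyte score 2 for surrogate-peer, and with the 3' to 5' ratio 3 in each comparison with maternal animals; leave-one-out gave 0 to 1 for the non-maternal animals and 0 to 0 in the others. The correlation of fold changes was 0.559 as the median over split maternal arrays and 0.772 to 0.894 leaving out 1 array. IRF7 turned from -1.21 to 0.0406 with 1 probe set per gene. Of the 20 genes named for the first comparison, COL11A1 alone passed in each of 13 leave-one-out fits. Its only tested probe set averaged 7.46 in maternal, 6.04 in peer and 6.18 in surrogate-peer animals. The non-maternal means thus lay near the filter threshold of 6.04, where signal is low. All 20 kept their sign, which the shared arrays make likely. Values that changed sign without passing in either setting were not counted as turned.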

Other observations

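Tests of the T cell score as a mark of lymphocyte RNA, and fits with the 3' to 5' covariate, were chosen after the result was seen, as was leaving out maternal arrays 2 and 5. Other gene groups of the first comparison gave values without a passing list. Of 29 oxidative phosphorylation genes 24 had positive fold changes, with 0 passing over all genes and 0 adjusted over the list alone; UQCRC2 (0.49), UQCRFS1 (0.41) and ATP5F1B (0.26; -0.03 at its other probe set) had the smallest p, and the score difference was 0.16 (exact permutation p = 0.0513, adjusted p = 0.183), or 0.08 without maternal array 5. Inflammatory mediators, with 12 measured, gave -0.11 (exact permutation p = 0.747), with SOD2 at -0.70 (0.31 at its other probe set) and IL1B at -0.64. Antimicrobial granule proteins gave -0.21 (exact permutation p = 0.410), with DEFA1, a neutrophil defensin, at -1.42. Cell cycle genes gave -0.07 (exact permutation p = 0.382), with MKI67 at -0.22. None of these 3 lists had a member past the threshold by either adjustment at its brightest probe set.

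Toll-like receptor sensing gave -0.37 (exact permutation p = 0.102), cytokines and their receptors -0.09 (0.354), MHC class II presentation -0.30 (0.166), adrenergic and cyclic AMP signalling 0.08 (0.410) and chemokine receptors and homing 0.03 (0.643). Of the markers of other blood cells, monocytes gave -0.29 (exact permutation p = 0.277), B cells -0.50 (0.113), plasma cells -0.21 (0.0326), dendritic cells 0.09 (0.534), granulocytes 0.04 (0.859), platelets -0.24 (0.443) and red cells -0.17 (0.419). MS4A7 was the only one of 20 monocyte markers to fall over all genes, and adjusted over the list alone 2 fell, with ITGAM (-0.39). FCER1A rose among 9 dendritic cell markers and CPA3 among 11 granulocyte markers, where CSF3R was down over the list alone. Mean and median differed in sign for dendritic cell markers (0.09 and -0.13) and for chemokine receptors and homing (0.03 and -0.07). With array centring, the scores of chemokine receptors and homing and of granulocyte markers changed sign.

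Several of these differences rested on maternal arrays 2 and 5. Without them toll-like receptor sensing gave -0.05 and MHC class II presentation -0.04, and the sign turned for inflammatory mediators (0.27), monocyte markers (0.11), antimicrobial granule proteins (0.04), red cell markers (0.02) and cytokines and their receptors (0.02). Leaving out 1 array gave -0.27 to 0.10 for inflammatory mediators, -0.36 to -0.06 for antimicrobial granule proteins, -0.13 to -0.01 for cell cycle genes, -0.53 to -0.22 for toll-like receptor sensing and -0.42 to -0.13 for MHC class II presentation. It gave -0.46 to -0.14 for monocyte, -0.01 to 0.22 for dendritic cell, -0.08 to 0.11 for granulocyte, -0.43 to -0.08 for platelet, -0.28 to -0.06 for red cell and -0.26 to -0.13 for plasma cell markers. For adrenergic and cyclic AMP signalling it gave 0.04 to 0.11, and for chemokine receptors and homing -0.004 to 0.07.

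The first pattern weighed was the excess of higher over lower probe sets in the non-maternal animals. Slopes within groups on the 3' to 5' ratio predicted a median of -0.104 ± 0.271 (jackknife SE) of the observed change over the 2107 probe sets, and slopes on the monocyte score 0.110 ± 0.123; a share of 0.5 lay more than 2 SE away in both, while a share of 0.25 did not. With these covariates 80.1% and 81.9% of calls were still higher. After quantile normalization 66.2% were higher, which neither removes the excess nor leaves it as it was. After centring each array on the median of its tested probe sets 56.7% were higher. Those medians ran from 7.65 to 7.71 in maternal and from 7.73 to 7.76 in other arrays. The median change over tested probe sets was 0.007 as deposited, -0.055 after centring and -0.022 after quantile normalization. Centring thus lowered all changes together, which by itself cuts the share of higher calls, so it cannot decide. An array-wide difference in the level or spread of values may account for some of the excess. How much is not settled by these settings. A lasting effect of rearing stays open as well and was not tested separately from these.

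A second pattern was the lower B cell marker score of the surrogate-peer animals. A general loss of lymphocyte RNA would lower T cell markers too, and the T cell score was higher by 0.38 ± 0.16 (SE), and by 0.17 without maternal arrays 2 and 5. T cell markers thus did not fall relative to the other RNA of these arrays. The test was chosen after the score was seen, and normalized values are relative, so a loss of T cells along with other cells cannot be excluded. The scores of NK and cytotoxic cell markers (-0.60) and plasma cell markers (-0.25) were lower in the same comparison, so a loss shared by other lymphocytes stays open. Within-group slopes on the 3' to 5' ratio predicted a difference of 0.34 ± 0.43 (jackknife SE), opposite in sign to the observed -0.88, but the error is too wide to exclude that ratio as a contributor. A smaller share of B cells in these animals may be behind the pattern. No cell counts were analysed here, and 2 of the 4 animals carried most of the difference. Title numbers were also lower in surrogate-peer than in maternal animals (exact permutation p = 0.0238, adjusted p = 0.0556). What these numbers stand for is not given. With the title number as a covariate fry called 0 lists in this comparison, and 0 without it, so the part of these numbers in the pattern is not settled.

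Other splits of the arrays were fitted to ask whether chance can be excluded. For the non-maternal against the maternal animals only the real split, 1 of 100, gave 2107 or more, and the highest other gave 13. A random grouping of these arrays thus seldom gives such a count. The real split also separates the spread of array values without overlap. The count therefore cannot tell a rearing difference from an array-wide one. For the F test 1 of 100 reached 23, and the highest other gave 1, with the same limit, and the 23 fell to 0 after array centring. For peer against maternal 3 of 100 reached 93, the real split included. This does not exclude chance, since other splits gave 4260 and 1013 and the 93 fell to 0 with only the arrays compared. The split with 4260 set maternal arrays 2 to 5 apart from maternal array 1 and the 4 peer arrays. That points to a structure of the samples in which maternal array 1 sits with the peer arrays. For surrogate-peer against maternal all 100 splits reached the real count of 0, with 687 as the highest other, where maternal array 1 and surrogate-peer array 2 changed places, again a structure of the samples, and for surrogate-peer against peer all 35 did, with 1 as the highest other; any split reaches a count of 0, so these splits do not test chance for either.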
